A study of Arabidopsis thaliana with 9 samples.

How the data were processed

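The series holds 9 RNA sequencing libraries, 3 each from plants with a PPD3 RNA interference transgene labelled dwarf, from such plants labelled large, and from wild type. Per the labels' protocols, seeds were stratified for 2 days at 4 °C and plants grown on soil at 22 and 20 °C with 12 h of light per day, RNA of aboveground tissue at bolting was extracted with a NucleoSpin RNA Plant kit, and libraries were made by the TruSeq RNA version 2 protocol, which does not mark strand. They were sequenced as paired reads of 100 bp on a DNBseq instrument to at least 4 Gb per sample. Per the submitters' processing notes, Trim Galore 0.4.1, STAR 2.7.0a and the TAIR10 genome build were used. The authors deposited counts of reads per gene, 1 file per library, as whole numbers with no normalization. The counting program, its annotation release and its strand setting are not given in the sources used here. Each file lists 33977 genes and 5 lines that name no gene, of which reads outside annotated genes and ambiguous reads hold counts. The 285 plastid and mitochondrial genes have 0 counts in all libraries.

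Gene counts per library summed to between 34660392 and 35217754. The 10 most abundant genes took 5.10 to 8.32% of the counts and 0.228 to 0.309% of reads were ambiguous. Symbols and positions came from the reference annotation of the TAIR10.1 assembly, to which 32548 of the IDs matched. It gave a position to 19864 of the genes tested. With R 4.3.3, the counts were normalized by TMM factors (0.935 to 1.05), filtered with filterByExpr, which left 19870 genes, and tested in edgeR 4.0.16 by the quasi-likelihood test, in a fit of all 9 libraries with 3 groups and no block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the count with at least a 2-fold change was given beside it. CPM are counts scaled by the library total and its TMM factor, and log2 CPM used a prior count of 2. Intervals are at 95%. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic of the same test. The intervals rest on them.

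Gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives, other than those said to be chosen later. The 21 lists were: PsbP domain family, photosystems and Rubisco, salicylic acid defence, pattern-triggered immunity and camalexin, jasmonate synthesis and response, abscisic acid, drought and cold, reactive oxygen and plastid stress, heat shock proteins, leaf senescence, glucosinolate pathway, flavonoid and anthocyanin pathway, circadian clock, flowering time, auxin response and transport, gibberellin and brassinosteroid, expansins and xyloglucan endotransglucosylases, cell cycle and DNA replication, DNA methylation and RNA silencing, and, as markers of tissues that the samples could hold in differing shares, floral organ, secondary wall and xylem, and root markers. They held 473 entries, of which 3 (PPD2, HSP17.6A and IPMDH1) were dropped because the reference gives the symbol to another locus. Lists were tested on log2 CPM with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 21 lists of a comparison. Camera with a correlation estimated for each list, and the rotation test fry, were run beside it. Counts of members are given over all genes tested and adjusted over the list alone.

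The genes named in each comparison are PPD3, the 5 with the largest positive and the 5 with the largest negative log2 fold change among called genes with a mean of at least 5 CPM, no overlap between the replicates and a symbol other than the locus code, and the 2 members of each list with the smallest p. List members were left out where the list had no called member, except for some of the lists that camera called. Genes named beyond this rule, namely the remaining called members of lists with few calls, further examples of the lists with the most calls, AT3G04650, and the sulfur and hypoxia genes, were chosen after their values were seen. Each named gene was checked for overlapping genes and for words of 50 bp of its exons found elsewhere in the genome. The word length was set to 50 bp after a first look with a longer word.

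The alternatives were size factors of DESeq2 or upper-quartile factors in place of TMM, no filter or a filter of at least 1 CPM in 3 samples, plastid, mitochondrial and rRNA genes left out, only the 2 groups compared in the fit, the replicate number as a block, the Wald test of DESeq2 1.42.0, limma voom with quality weights, and each of the 9 libraries left out in turn. After seeing the data, steps along chromosomes were searched for in each library. The log2 ratios to the WT mean of genes with at least 5 CPM, limited to 1.5 in size, were split by binary segmentation with segments of at least 15 genes, a step of at least 0.2 and the 99.9% quantile of 1000 permutations. Calls were then repeated with genes of the raised regions left out, and with the median step of each region in each library entered as an offset. Changes shared by the comparisons with WT were set beside 20 simulations of unchanged groups, in which all 9 libraries were drawn from the WT means.

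The tests were tested on simulated data drawn from the means and library sizes of the real libraries, with 50 genes changed at each of 1.5-, 2-, 4- and 8-fold. For dwarf against WT, with 19741 genes, edgeR recovered 11, 26, 44 and 48 of them, with 11 false calls among 140. For large against WT, with 19722 genes, it recovered 3, 35, 42 and 48, with 6 false among 134, and for dwarf against large, with 19761 genes, 7, 30, 44 and 49, with 6 false among 136. Camera called the raised list and 0 of 20 unchanged lists in each. Genes were simulated independently of each other, so this does not test camera's preset correlation on lists whose members move together. The segmentation found 20 of 20 simulated steps of 1.5-fold over 200 of 2197 genes, with the breakpoint misplaced by at most 2 genes, and 0 steps in unchanged chromosomes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The values of 1 gene that passed edgeR's test are not reported here.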

Results

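RNA was sequenced from the aboveground tissue of Arabidopsis thaliana plants of the Col-0 accession, collected when the plants were bolting. The labels name 3 groups of 3 biological replicates. In 2 of the groups the plants carried an RNA interference transgene against PPD3 (AT1G76450), a PsbP domain protein of the chloroplast, and are labelled dwarf or large by phenotype. The remaining group was wild type (WT). The title of the series names sensory plastids, growth, defence and epigenetic responses, so the comparisons ask how the transcripts of the dwarf plants and of the large plants differed from WT and from each other. The counts assigned to genes summed to 34864184, 35217754 and 34660392 in libraries 1, 2 and 3 labelled dwarf, to 34991725, 34829031 and 34725888 in those labelled large, and to 34775560, 34747447 and 34804491 in those labelled WT. Of 33977 genes in the files, 19870 had enough counts to be tested. On the first principal component, which held 38.2% of the variance, dwarf 1 lay at -77.5, dwarf 2 at -41.0 and large 2 at -16.9, and the other 6 libraries lay above 0.

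PPD3, the gene that the transgene targets, lies on chromosome 1 between 28684551 and 28686244 of the TAIR10.1 assembly. Its level was 115, 100.3 and 91.1 CPM (counts scaled to a common library total) in WT 1, 2 and 3. It was 86.7, 77.9 and 108 CPM in large 1, 2 and 3, and 87.6, 128 and 96.5 CPM in dwarf 1, 2 and 3. The group means were 102 ± 12.0 CPM in WT, 90.9 ± 15.5 CPM in the libraries labelled large and 104 ± 21.5 CPM in those labelled dwarf (mean ± SD, n = 3 each). None of the 3 differences passed edgeR's quasi-likelihood test. The log2 fold change against WT was -0.17 (SE 0.17, 95% interval -0.56 to 0.23, adjusted p = 0.708) for large and 0.03 (SE 0.17, 95% interval -0.36 to 0.42, adjusted p = 0.934) for dwarf. Between dwarf and large it was 0.20 (SE 0.17, 95% interval -0.20 to 0.59, adjusted p = 0.558). The value for dwarf against WT took a negative sign under 5 alternatives, among them the fits without dwarf 2 (-0.15) and without WT 3 (-0.05). The lowest of the 5 was -0.33 (adjusted p = 0.327), with the median step of the raised chromosome region that holds PPD3, described below, taken out. A fall of PPD3 was thus not detected, and the libraries are called by their labels throughout. Reads of a hairpin transgene, if counted at PPD3, cannot be separated from those of the gene in these counts, and 3.78% of the gene overlaps AT1G76460 on the opposite strand.

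**Figure D1:**
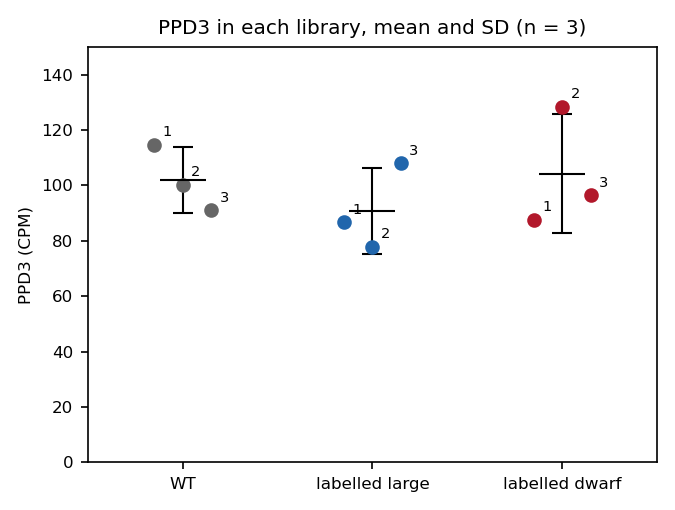
CPM of PPD3 in each of the 9 libraries (points), with the mean and SD of each group of 3. The group means are 102 CPM in WT, 90.9 CPM in the libraries labelled large and 104 CPM in those labelled dwarf.

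Long runs of neighbouring genes were raised together in the RNAi libraries. Against the mean of the WT libraries, genes of the first 9.03 Mb of chromosome 4 (2895 to 9033648) had a median ratio of 1.48 to 1.51 in 5 of the 6 RNAi libraries and of 1.98 in dwarf 1. Genes of the first 1.13 Mb of chromosome 3 (8723 to 1136397) had a median ratio of 1.46 to 1.49 in large 1, 2 and 3 and in dwarf 1. On chromosome 1, genes of the last 4.79 Mb (25631689 to 30424152), where PPD3 lies, had a median ratio of 1.47 in dwarf 1 and 1.48 in dwarf 2, and genes of the first 11.7 Mb (3631 to 11719988) a median ratio of 1.46 in dwarf 3. A search for steps along each chromosome, set up after the data were seen, found 14 raised segments in the 6 RNAi libraries and 0 in the WT libraries. In the WT libraries the median log2 ratios of the 4 regions lay between -0.03 and 0.02. The 4 regions hold 1024, 291, 1092 and 2479 of the genes tested, in the order given. Each gene named hereafter that lies in such a region is marked, because its fold change holds the step of its region where the libraries compared carry it. Marking genes, leaving out the regions or taking out their steps deals with genes inside the regions only. Whether the raised segments also changed genes outside them was not tested, and the groups compared differ in these segments.

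**Figure D2:**
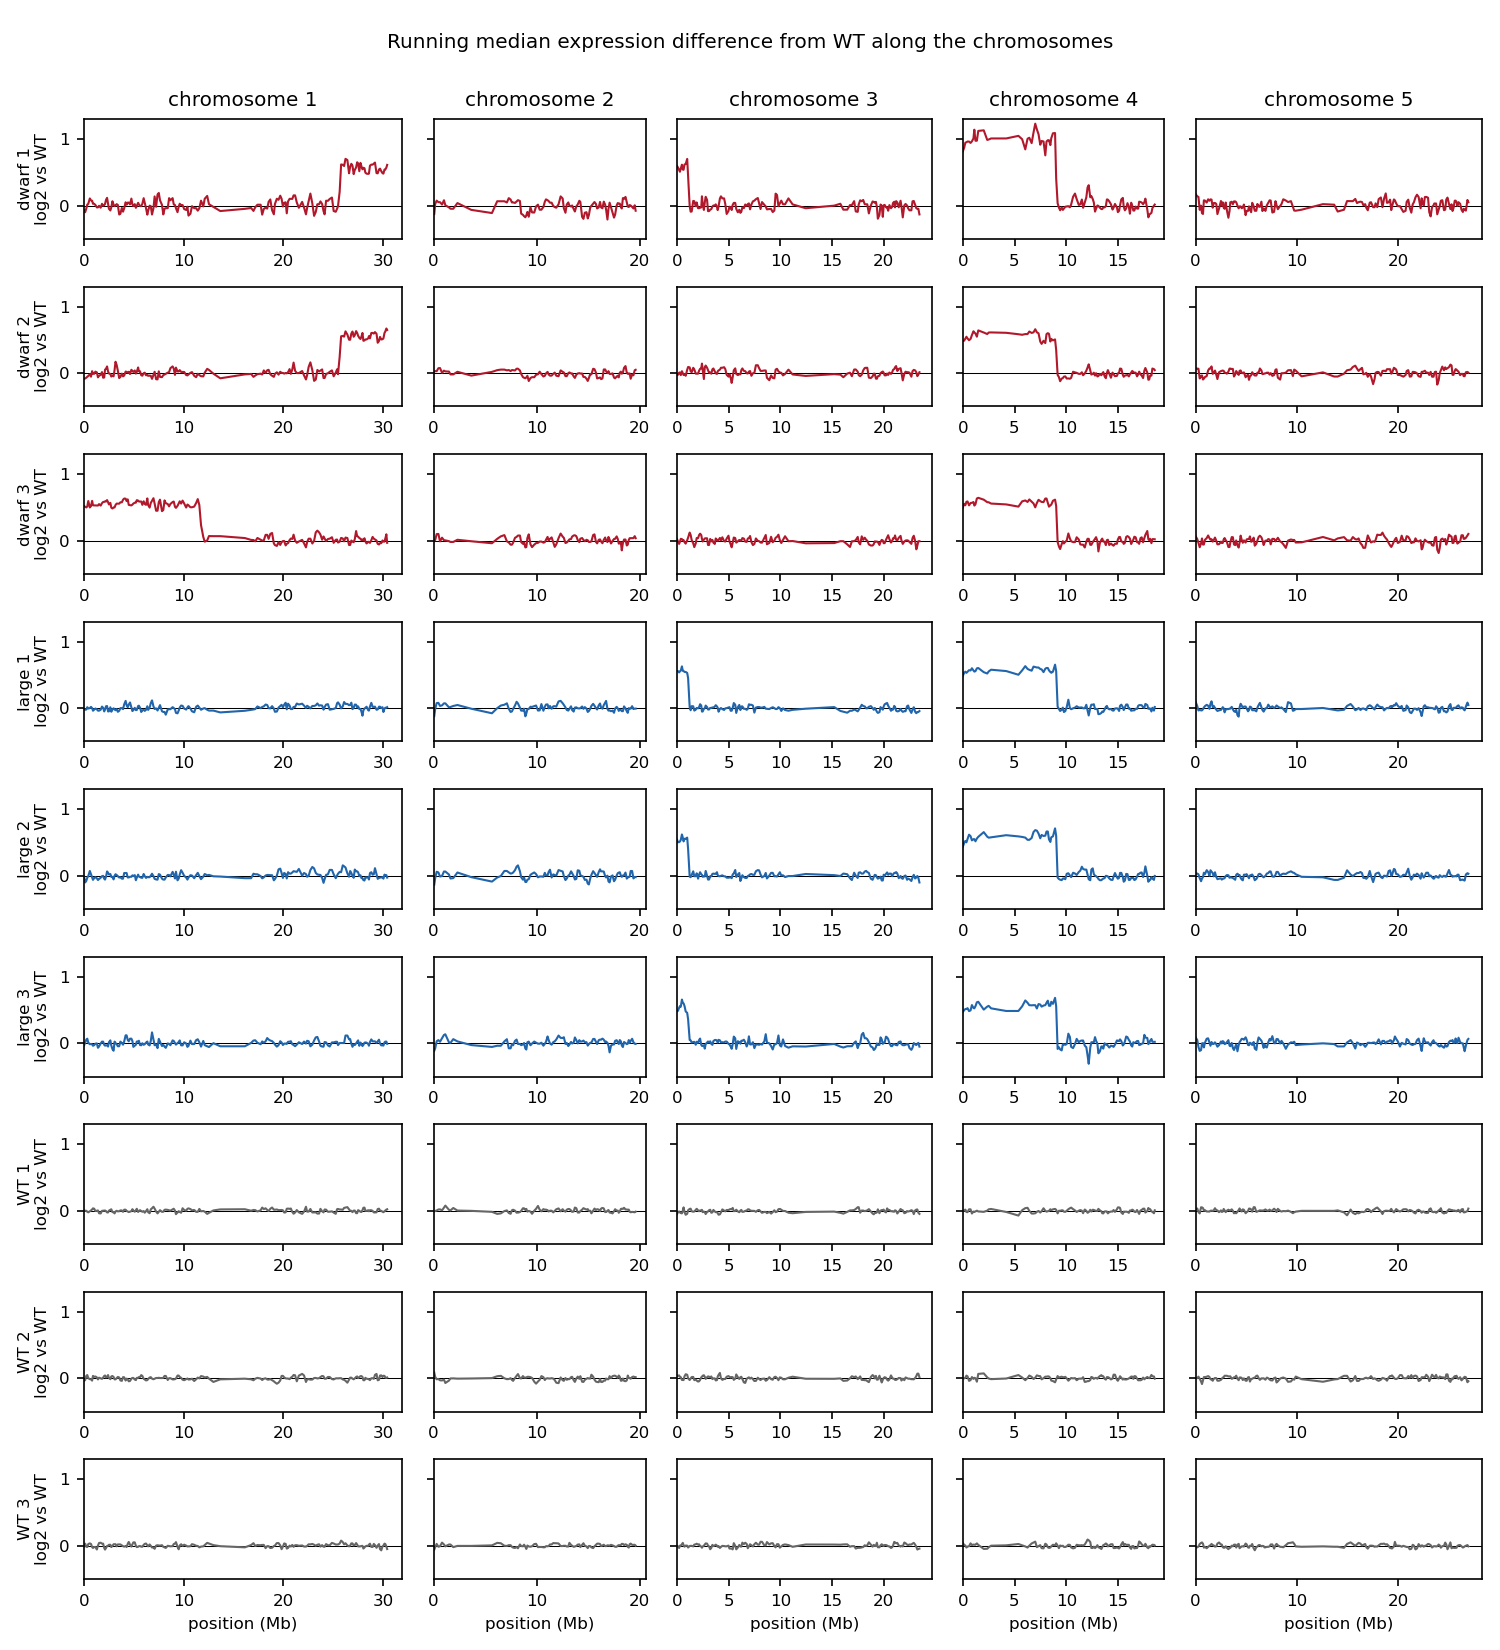
Running median, over 41 neighbouring genes, of the log2 ratio to the mean of the WT libraries along the 5 chromosomes (position in Mb), for each of the 9 libraries. All 6 RNAi libraries lie above 0 over the first 9.03 Mb of chromosome 4, and the WT libraries stay near 0 throughout.

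The library kit does not mark strand, so reads where genes overlap cannot be told apart by strand, and how the counting treated them is not given in the sources used here. This makes the values of MYC2 (98.5% of the gene overlapped), F3H (94.5%), PSAH1 (49.0%), PSAE1 (33.4%), BZR1 (24.5%), COR15B (25.4%), GSTU10 (22.6%), G6PD4 (20.4%) and CDKB1;2 (17.41%) uncertain. Stretches of 50 bp that occur elsewhere in the genome make up 7.23% of PRXCA, 7.11% of SAUR24, 6.07% of Prx37, 5.23% of AAE12, 5.19% of SAUR21 and 2.89% of CYP79F2, whose values hold that uncertainty.

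In the libraries labelled dwarf, transcripts of 9 of 23 abscisic acid, drought and cold genes tested were lower than in WT, and the largest rises were those of single genes. COR15A (AT2G42540), a cold-regulated chloroplast protein, fell from 868 ± 168 CPM in WT to 183 ± 17.56 CPM (mean ± SD, n = 3 each), a log2 fold change of -2.25 (SE 0.18, adjusted p = 0.00272). RD29A (AT5G52310), induced by desiccation and cold, had a log2 fold change of -2.05 (SE 0.19, adjusted p = 0.00486). The other largest falls were those of AAE12 (AT1G65890), an acyl-activating enzyme, at -2.34 (SE 0.53), XTH31 (AT3G44990), a xyloglucan-modifying enzyme of the cell wall, at -1.85 (SE 0.24), and 4CL8 (AT5G38120), a 4-coumarate-CoA ligase-like enzyme, at -1.84 (SE 0.37). The largest rises were those of Prx37 (AT4G08770, chromosome 4 region), a class III peroxidase, at 4.91 (SE 1.00), PRXCA (AT3G49110), another such peroxidase, at 3.3 (SE 0.48), and EDA36 (AT4G13890, chromosome 4 region) at 3.05 (SE 0.61). GSTU10 (AT1G74590, end of chromosome 1), a glutathione S-transferase, and RLP20 (AT2G25440), a receptor-like protein, each rose by 2.91 (SE 0.74 and 0.58). With the median step of the region taken out EDA36 stood at 2.27 and GSTU10 at 2.41, and neither passed the test. Prx37 varied widely within the group, at 38.5 ± 39.3 CPM against 1.28 ± 0.544 CPM in WT. PRXCA rose from 13.6 ± 5.0 to 134 ± 65.3 CPM.

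By edgeR's quasi-likelihood test, 1740 of 19870 genes differed between dwarf and WT at an adjusted p under 0.05, of which 1299 rose and 441 fell, and 556 changed at least 2-fold (455 up and 101 down). Of the 1299 genes that rose, 571 lie in the chromosome 4 region, which holds 5.15% of the tested genes, 144 in the region at the start of chromosome 1, 122 in that at its end and 13 in the chromosome 3 region. Outside the 4 regions 449 genes rose and 421 fell. The replicates of the 2 groups did not overlap for 28.9% of the genes tested, where chance gives 10%. In 2 alternatives chosen after seeing the data, 587 genes (369 up and 218 down) were called with the regions left out and 855 (422 up and 433 down) with the median step of each region taken out. The share of rises among the calls, 74.7%, was 57.9% with upper-quartile factors (1050 of 1812 up), and 467 genes were called with only the 2 groups in the fit, 3118 by DESeq2 and 4626 by limma voom. Leaving out 1 library gave 266 genes without WT 1, 293 without WT 2, 724 without WT 3, 964 without large 1, 1110 without dwarf 2 and 4477 without dwarf 3.

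Of the 21 gene lists, 9 were called in dwarf against WT by camera with a preset correlation, 3 up and 6 down, and 0 with a correlation estimated from the data. The clearest fall was in the abscisic acid, drought and cold list, of which 9 of 23 members fell and none rose (14 down when adjusted over the list alone). Beside COR15A and RD29A these were COR15B (-1.56), CBF3 (-1.34), KIN2 (-1.21), P5CS1 (-1.06), COR47 (-0.99), ERD10 (-0.85) and RD22 (-0.62), with COR47 and ERD10 in the region at the start of chromosome 1 that was raised in dwarf 3. With its step taken out these 2 stood at -1.17 and -1.06 and passed the test. The list's median was -0.82 and its adjusted p 3.80e-11, with a range of 3.69e-14 to 0.301 over its alternatives, the upper end being the adjusted p with an estimated correlation. The directional rotation test fry, which asks whether the members move 1 way, also called this list alone (adjusted p = 0.0131).

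The photosystem and Rubisco list lay lower, with 34 of 39 members negative and a median of -0.49 (adjusted p = 3.26e-08, range 1.49e-13 to 0.764 over its alternatives, the upper end with an estimated correlation). A single member, the photosystem I subunit gene PSAH1, fell at -0.77 (adjusted p = 0.0290, 0 members when adjusted over the list alone), and PSAE1 stood at -0.72 (adjusted p = 0.0670). Of 27 genes of auxin response and transport 3 fell, 1 rose and 22 were negative (2 up and 9 down when adjusted over the list alone, median -0.85, adjusted p = 7.15e-06). The growth-related SAUR21 fell by 1.34 and SAUR24 by 1.01 and the auxin repressor IAA7 by 0.66. All 15 secondary wall and xylem genes tested were negative (median -0.42, adjusted p = 3.32e-05, 4 down when adjusted over the list alone), among which the xylem protease gene XCP1 fell by 0.76 and COBL4 stood at -0.89 (adjusted p = 0.0614). Of 23 jasmonate genes 17 were negative and 2 fell (3 when adjusted over the list alone, adjusted p = 0.00236), namely CORI3 (-1.30) and the transcription factor MYC2 (-0.58). Of 30 gibberellin and brassinosteroid genes 20 were negative (adjusted p = 0.00288), of which the DELLA gene RGL1 (-0.77) and the brassinosteroid synthesis gene CPD (-0.58) fell and BZR1 (0.62, end of chromosome 1), a brassinosteroid-response factor, rose (0.23 and not called with its regional step taken out), 3 down and 1 up when adjusted over the list alone. Outside the 4 regions, with the normalization of all genes kept, the adjusted p of that last list by camera was 0.0521. The list kept its call when the libraries were normalized and fitted again without the regions. With an estimated correlation the adjusted p was 0.764 for these auxin, secondary wall, jasmonate and gibberellin lists, the highest of their alternatives. The lowest values were 6.36e-07, 4.35e-08, 3.95e-05 and 0.000402. Without dwarf 3 the adjusted p of the jasmonate list was 0.0508.

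Cell cycle and DNA replication genes lay higher in dwarf than in WT, with 24 of 27 positive and a median of 0.36 (adjusted p = 0.000790, range 1.01e-05 to 0.764 over its alternatives, the upper end with an estimated correlation). In this list 3 members rose, also when adjusted over the list alone: the replication helicase subunit gene MCM7 (0.71, chromosome 4 region), the mitotic cyclin gene CYCB1;1 (0.68) and CDKB2;1 (0.59, end of chromosome 1). With the median step of the region taken out, MCM7 stood at 0.01 and CDKB2;1 at 0.22, and neither passed the test. The salicylic acid defence list (21 of 22 positive, median 0.61, adjusted p = 0.0279) and the list of pattern-triggered immunity and camalexin (18 of 19 positive, median 0.69, adjusted p = 0.0461) were called up with 0 members past edgeR's test over all genes. When adjusted over the list alone, 0 and 4 members were up. WRKY38 stood at 1.47 (adjusted p = 0.0813), SARD1 at 1.25 (adjusted p = 0.101, end of chromosome 1), FRK1 at 2.09 (adjusted p = 0.0700) and WRKY22 at 1.69 (adjusted p = 0.0535, chromosome 4 region). With an estimated correlation the adjusted p was 0.764 for both, the highest of their alternatives, which began at 0.000187 and 0.00232. Both calls were lost without dwarf 1, without dwarf 2 and without WT 1, and that of pattern-triggered immunity also without WT 2, with adjusted p up to 0.478.

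Single genes rose or fell in lists that were not called. In the list of reactive oxygen and plastid stress (adjusted p = 0.612), the light-stress genes ELIP1 (0.96) and ELIP2 (2.29, chromosome 4 region) rose and UPOX (-0.48) fell. Among heat shock genes (adjusted p = 0.372), HSFA7A (1.44), MBF1C (0.85) and HSP101 (0.65, end of chromosome 1) rose and HSP18.2 (-0.99) fell. In the glucosinolate pathway (adjusted p = 0.852), MAM3 (2.19), which elongates the side chain of methionine-derived glucosinolates, and CYP79F2 (1.61, start of chromosome 1), of their core pathway, rose, and the myrosinase gene TGG2 (-0.99) fell. In the flowering time list (adjusted p = 0.338), the floral repressor TEM1 (0.77, start of chromosome 1) rose and MAF4 stood at -1.63 (adjusted p = 0.0505). Among expansins and xyloglucan endotransglucosylases (adjusted p = 0.0576), XTH9 (1.54, chromosome 4 region) rose and EXPB1 (-1.07), EXPA8 (-0.96) and EXPA3 (-0.68) fell. In the list of DNA methylation and RNA silencing (adjusted p = 0.746), RDR2 (1.16, chromosome 4 region), SUVH9 (0.48, chromosome 4 region) and NRPD1 (0.56), all of the RNA-directed pathway, rose, and the DNA demethylase gene ROS1 (-0.74) fell. With the regional step taken out, RDR2 stood at 0.44, XTH9 at 0.86, SUVH9 at -0.24, HSP101 at 0.27, TEM1 at 0.61 and ELIP2 at 1.53, and none of these 6 passed the test, while CYP79F2, at 1.40, did.

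Adjusted over each of these lists alone, 4 genes of the reactive oxygen list were up and 1 down, 5 heat shock genes up and 1 down, 4 glucosinolate genes up and 2 down, 1 flowering time gene up and 1 down, 2 expansin and xyloglucan genes up and 3 down, and 3 methylation genes up and 1 down. The adjusted p in dwarf against WT was 0.137 for the PsbP domain family, 0.396 for leaf senescence, 0.465 for root markers, 0.746 for the circadian clock, 0.746 for floral organ markers and 0.852 for the flavonoid pathway, with 0 members past edgeR's test over all genes in each. Adjusted over the list alone, 1 root marker was up, 1 floral organ marker was down and the other 4 lists had 0. Here and in the other comparisons, 2 of 16 floral organ markers and 3 of 12 root markers were tested. The values of these lists thus rest on few genes and are a weak check of tissue shares. Median, mean and test differed in sign for leaf senescence, the glucosinolate pathway and the circadian clock. COR15A, RD29A, COR15B, COR47, KIN2, XTH31, PRXCA, MAM3, CYP79F2, MCM7, RDR2, TEM1 and XTH9 passed edgeR's test without any of the 9 libraries in turn. Their adjusted p was up to 0.0477. Of the genes named so far in this comparison, each other call was lost without at least 1 library. As given above, MCM7, RDR2, TEM1 and XTH9 were not called with the regional step taken out.

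**Figure D3:**
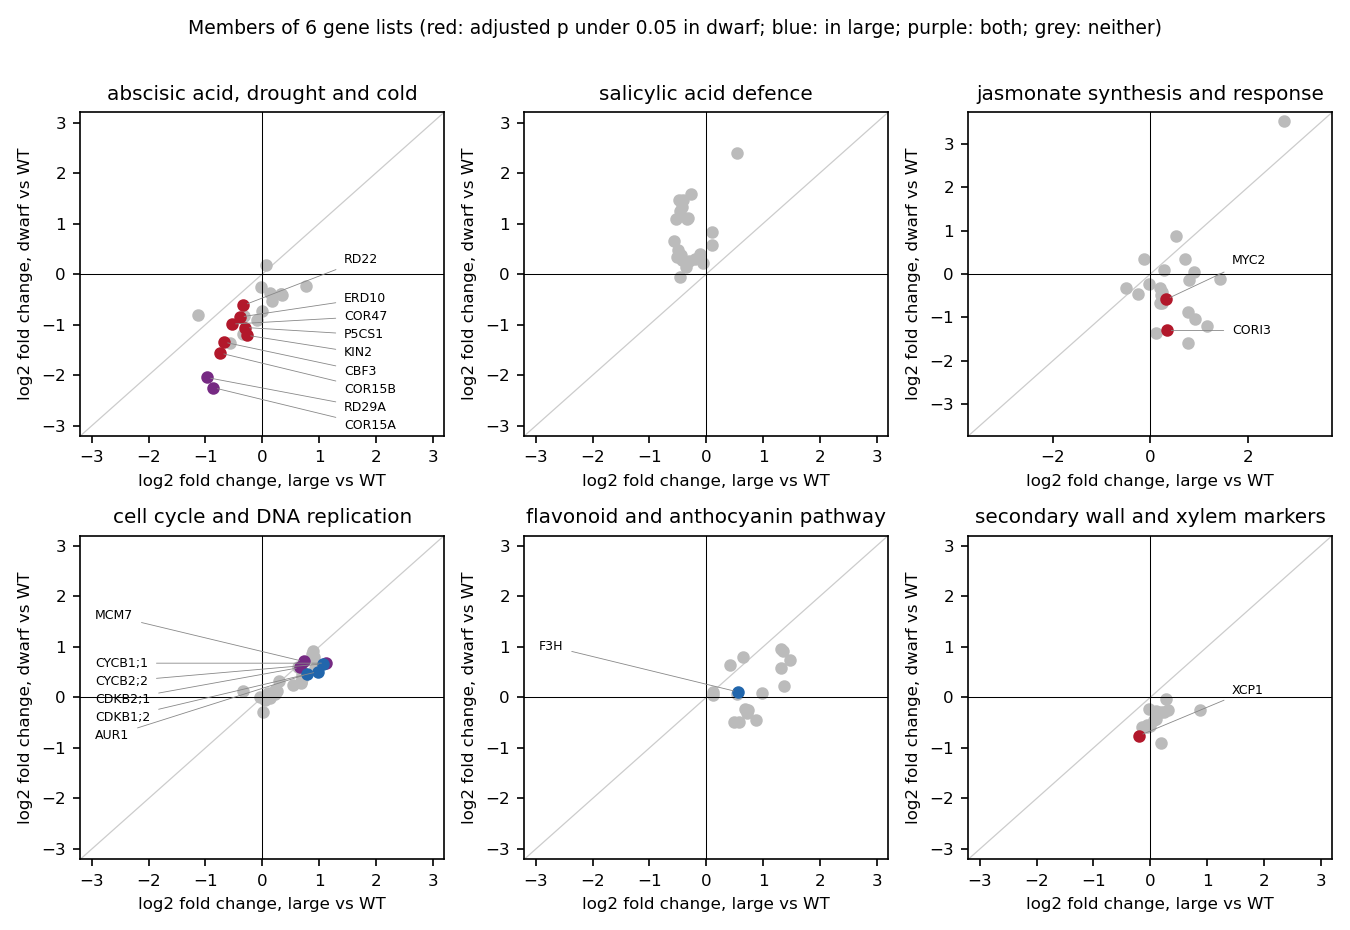
Log2 fold changes of the members of 6 gene lists, large against WT on the horizontal axis and dwarf against WT on the vertical axis, with a point per gene, coloured where edgeR's test called it, and the line of equal change. In the abscisic acid list 22 of 23 members are negative in dwarf, and in the cell cycle list 25 of 27 are positive in large.

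In the libraries labelled large, 6 of 27 cell cycle genes and 1 of 18 flavonoid genes tested were higher than in WT by edgeR's test over all genes. Camera called both lists up with a preset correlation and neither with an estimated one (adjusted p = 0.542 for each). The largest rises were those of single genes. ACO1 (AT2G19590), an ethylene-forming enzyme, rose from 2.22 ± 1.55 to 14.4 ± 3.84 CPM (mean ± SD, n = 3 each), a log2 fold change of 2.7 (SE 0.47, adjusted p = 0.0225). PRXCA rose by 2.63 (SE 0.47), LBD41 (AT3G02550, chromosome 3 region), a transcription factor gene induced by low oxygen, by 2.53 (SE 0.42), GH9B13 (AT4G02290, chromosome 4 region), a glycosyl hydrolase, by 2.41 (SE 0.26) and OXS3 (AT5G56550), named for oxidative stress, by 2.39 (SE 0.25). With the regional step taken out LBD41 stood at 1.98 and did not pass the test, and GH9B13 stood at 1.83 and did. The falls were smaller. BBX16 (AT1G73870, end of chromosome 1), a B-box protein, had a log2 fold change of -1.06 (SE 0.22), RD29A of -0.98 (SE 0.18), COR15A of -0.86 (SE 0.18), the zinc finger gene ZFP8 (AT2G41940) of -0.60 (SE 0.12) and the RING finger gene BRG3 (AT3G12920) of -0.60 (SE 0.12). COR15A stood at 478 ± 75.8 CPM, between the levels of WT and dwarf.

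By edgeR's test 838 genes differed between large and WT, of which 773 rose and 65 fell, and 263 changed at least 2-fold (253 up and 10 down). Of the 773 rises, 329 lie in the chromosome 4 region, 62 in the chromosome 3 region, 25 at the start of chromosome 1 and 21 at its end. Outside the 4 regions 336 genes rose and 54 fell. The regions on chromosome 1 were raised in no library labelled large (median log2 fold changes -0.009 and -0.002). Leaving them out therefore also drops calls that hold no regional step. The replicates of the 2 groups did not overlap for 33.6% of the genes tested, where chance gives 10%. With the regions left out 265 genes were called (236 up and 29 down), and 327 with the regional steps taken out (281 up and 46 down), both chosen after seeing the data. The share of rises, 92.2%, was 76.9% among the 2205 genes called with only the 2 groups in the fit, and DESeq2 called 1792 and limma voom 4192. The count was 9 without WT 1, 9 without WT 2, 548 without WT 3, 53 without large 1, 155 without large 2, 88 without large 3, 1549 without dwarf 1 and 1599 without dwarf 3.

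Camera called 8 of the 21 lists in large against WT, 4 up and 4 down, and 0 with an estimated correlation. Of 27 cell cycle and DNA replication genes 25 were positive and 6 rose (16 when adjusted over the list alone, median 0.68, adjusted p = 2.30e-08). They included the mitotic cyclin genes CYCB1;1 (1.12) and CYCB2;2 (1.06), the kinase gene CDKB1;2 (0.98) and MCM7 (0.73, chromosome 4 region), which stood at 0.15 with its regional step taken out. All 18 flavonoid and anthocyanin genes tested were positive (median 0.70, adjusted p = 0.000150, 6 up when adjusted over the list alone), of which F3H rose by 0.56 and UGT75C1 stood at 1.31 (adjusted p = 0.0655, chromosome 4 region). Of 38 genes of DNA methylation and RNA silencing 28 were positive (median 0.20, adjusted p = 0.00517), with RDR2 (1.02) and SUVH9 (0.51) the 2 that rose, also when adjusted over the list alone. Both lie in the chromosome 4 region, and with its step taken out they stood at 0.45 and -0.06 and did not pass the test. Of 10 heat shock genes 9 were positive and HSP101 (0.81) rose (3 when adjusted over the list alone, median 0.70, adjusted p = 0.0118), with MBF1C at 0.69 (adjusted p = 0.0706). With an estimated correlation the adjusted p was 0.542 for these 4 lists, the highest of their alternatives, whose lowest values were 1.44e-10, 2.12e-06, 0.000651 and 0.00342 in the order given. Fry called the same 4 lists, each with an adjusted p of 0.0422.

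The 4 lists called down in large against WT were photosystems and Rubisco (32 of 39 negative, median -0.33, adjusted p = 0.000333), abscisic acid, drought and cold (16 of 23 negative, median -0.30, adjusted p = 0.000574), salicylic acid defence (19 of 22 negative, median -0.38, adjusted p = 0.00148) and auxin (20 of 27 negative, median -0.43, adjusted p = 0.00293). Over all genes 0, 2, 0 and 0 of their members fell, and adjusted over the list alone 0, 4, 0 and 0. Against the direction of its list, 1 auxin gene rose over all genes (0 when adjusted over the list alone). In the auxin list IAA29 stood at -1.95 (adjusted p = 0.0992). EDS1 stood at -0.44 (adjusted p = 0.387) and WRKY54 at -0.35 (adjusted p = 0.230). With an estimated correlation the adjusted p was 0.847, 0.542, 0.847 and 0.796 for the 4 lists, each the highest of its alternatives. The lowest were 5.34e-06, 5.88e-05, 3.70e-08 and 0.000559. Without large 2 the adjusted p was 0.0910 for photosystems, 0.0644 for auxin and 0.0644 for heat shock, and without large 3 it was 0.126 for salicylic acid defence.

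Among lists not called in large against WT, HSFA2 (1.90) rose in the reactive oxygen list (adjusted p = 0.343), where ELIP1 stood at 0.57 (adjusted p = 0.105). GASA4 (0.77) rose among gibberellin and brassinosteroid genes (adjusted p = 0.518), where GID1A stood at 0.26 (adjusted p = 0.231), and XTH9 (1.5, chromosome 4 region, 0.92 and not called with the step taken out) and XTH16 (1.02) rose among expansins and xyloglucan enzymes (adjusted p = 0.789). Adjusted over these 3 lists alone, 1, 1 and 3 genes were up. The adjusted p was 0.0661 for jasmonate, with 19 of 23 positive, 0.168 for pattern-triggered immunity, 0.277 for the PsbP domain family and 0.518 for each of the circadian clock, flowering time and root markers. It was 0.549 for leaf senescence, 0.641 for secondary wall, 0.652 for the glucosinolate pathway, whose mean and median differed in sign, and 0.927 for floral organ markers. Of these 10 lists 0 members passed over all genes, and adjusted over the list alone 1 leaf senescence gene was up and 0 in the other 9. Of the genes named so far in this comparison, each call was lost without at least 1 library, that of OXS3 without WT 1 and that of GH9B13 without WT 1 or WT 2, with the adjusted p of these 2 up to 0.0647.

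Compared directly, the libraries labelled dwarf had less transcript than those labelled large of a ligase-like, a sulfur-deficiency and a cell wall gene and of the cold genes COR15A and RD29A, and more of the glucosinolate genes MAM3 and CYP79F2. 4CL8 stood at 2.68 ± 1.53 CPM in dwarf, 16.1 ± 4.35 CPM in large and 9.54 ± 1.86 CPM in WT (mean ± SD, n = 3 each), a log2 fold change between dwarf and large of -2.59 (SE 0.37, adjusted p = 0.0353). ATSDI1 (AT5G48850), induced by sulfur deficiency, stood at -1.83 (SE 0.27), XTH31 at -1.81 (SE 0.24), BT1 (AT5G63160), a BTB and TAZ domain protein, at -1.40 (SE 0.17) and COR15A at -1.39 (SE 0.18). The largest positive values were those of MAM3 (1.77, SE 0.22, adjusted p = 0.0278), TIM17-1 (AT1G20350), a mitochondrial import subunit, at 1.60 (SE 0.26), and the cation exchanger gene CHX16 (AT1G64170) at 1.52 (SE 0.24). G6PD4 (AT1G09420), a glucose-6-phosphate dehydrogenase, stood at 1.39 (SE 0.23) and the zinc transporter gene ZIP5 (AT1G05300) at 1.38 (SE 0.20). TIM17-1, G6PD4 and ZIP5 lie in the region at the start of chromosome 1 that was raised in dwarf 3, and without the regional step they stood at 1.49, 1.27 and 1.27 and did not pass the test.

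By edgeR's test 129 genes differed between dwarf and large, 54 higher and 75 lower in dwarf, and 63 differed at least 2-fold (23 higher and 40 lower). Of the 54 higher genes, 23 lie at the start of chromosome 1 and 7 at its end, and of the 75 lower genes 13 lie in the chromosome 3 region. Outside the 4 regions 22 were higher and 53 lower. The replicates of the 2 groups did not overlap for 20.0% of the genes tested, where chance gives 10%. With the regions left out 67 genes were called (24 higher and 43 lower), and 169 with the regional steps taken out (42 higher and 127 lower). The share of higher calls, 41.9%, was 29.3% with upper-quartile factors (54 higher and 130 lower). EdgeR called 0 genes with only the 2 groups in the fit, where 2868 had an unadjusted p under 0.05, and 0 with the replicate number as a block, where 3857 did, while DESeq2 called 1677 and limma voom 3781. Leaving out 1 library gave 0 genes by edgeR without dwarf 2, large 1 or WT 1 (3167, 2684 and 3463 at an unadjusted p under 0.05), 4 without large 3, 6 without large 2, 9 without WT 3, 14 without WT 2, 207 without dwarf 1 and 3236 without dwarf 3. Each named call of this comparison was lost without at least 6 of the 9 libraries in turn.

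Camera called 12 lists in dwarf against large, 2 up and 10 down, and 0 with an estimated correlation. All 22 salicylic acid defence genes tested were positive in this comparison (median 0.91, adjusted p = 8.34e-08, 8 up when adjusted over the list alone), with WRKY38 at 1.87 (adjusted p = 0.0883) and SARD1 at 1.71 (adjusted p = 0.0893, end of chromosome 1). All 19 genes of pattern-triggered immunity and camalexin were positive (median 0.62, adjusted p = 0.000114, 3 up when adjusted over the list alone), with FRK1 at 2.47 (adjusted p = 0.0923) and WRKY29 at 1.16 (adjusted p = 0.0680). In both lists 0 members passed edgeR's test over all genes. Of 23 abscisic acid, drought and cold genes 21 were negative (median -0.72, adjusted p = 1.66e-07), of which COR15A and RD29A (-1.07) were called over all genes and 7 when adjusted over the list alone. All 15 secondary wall and xylem genes were negative (median -0.53, adjusted p = 2.71e-07, 9 when adjusted over the list alone), with XCP1 at -0.56 (adjusted p = 0.0688) and COBL4 at -1.09 (adjusted p = 0.0770). Of 23 jasmonate genes 19 were negative (median -0.85, adjusted p = 1.19e-06, 12 when adjusted over the list alone), of which MYC2 (-0.91) was called over all genes and CORI3 stood at -1.65 (adjusted p = 0.0515). Of 18 flavonoid genes 16 were negative (median -0.73, adjusted p = 0.000114, 0 when adjusted over the list alone), with F3H at -0.45 (adjusted p = 0.0956) and TT7 at -1.08 (adjusted p = 0.142). With an estimated correlation the adjusted p was 0.4997 for these 6 lists, the highest of their alternatives. The lowest were 1.91e-12, 1.03e-06, 3.07e-10, 1.81e-09, 4.33e-09 and 4.69e-05 in the order given.

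A further 6 lists were called down in dwarf against large with 0 members past edgeR's test over all genes. These were photosystems (32 of 39 negative, adjusted p = 0.00519), expansins and xyloglucan enzymes (16 of 23, adjusted p = 0.00681), gibberellin and brassinosteroid (21 of 30, adjusted p = 0.00711), the cell cycle (23 of 27, adjusted p = 0.00789), DNA methylation and RNA silencing (29 of 38, adjusted p = 0.0129) and auxin (20 of 27, adjusted p = 0.0140). Adjusted over the list alone, 2 gibberellin and brassinosteroid genes and 1 auxin gene were lower and 0 in the other 4 lists. With an estimated correlation the adjusted p was 0.715, 0.701, 0.4997, 0.715, 0.4997 and 0.701, and the lowest of their alternatives were 2.38e-08, 1.75e-05, 0.00122, 0.00142, 0.00180 and 0.000727. Without dwarf 1 the calls of photosystems, expansins, gibberellin, the cell cycle and auxin were lost, without large 1 those of photosystems, DNA methylation and auxin, and without large 3 those of photosystems and the cell cycle, with an adjusted p of up to 0.965 for photosystems.

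Of the lists not called between dwarf and large, the glucosinolate pathway (adjusted p = 0.778) held MAM3 and CYP79F2 (1.17, start of chromosome 1) as genes higher in dwarf, with 4 higher and 1 lower when adjusted over the list alone, and the reactive oxygen list (adjusted p = 0.998) held UPOX (-0.72) as lower, also when adjusted over the list alone, with GUN1 at 0.30 (adjusted p = 0.134). The adjusted p was 0.0691 for flowering time, 0.0729 for leaf senescence, 0.499 for heat shock, 0.571 for floral organ markers, 0.723 for the PsbP domain family, 0.751 for the circadian clock and 0.868 for root markers, with 0 members past edgeR's test over all genes in each. Adjusted over the list alone, 1 heat shock gene was higher and 3 lower, 1 flowering time gene higher and 2 lower, and 1 root marker higher and 1 lower, with 0 in the other 4 lists. Median, mean and test differed in sign for the reactive oxygen, glucosinolate and root lists.

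The changes of dwarf and large from WT were compared across genes, which are not independent replicates. Of the genes tested, 489 rose in both, where independent lists of these sizes would share 50.5, and 26 fell in both, where 1.44 would be shared. Outside the 4 regions 155 rose in both (10.1 if independent) and 24 fell in both (1.52 if independent), and 1 gene went opposite ways. Across all genes the correlation of the log2 fold changes was 0.615. Unchanged groups simulated 20 times gave a mean of 0.507 (SD 0.0189), since both comparisons share their controls. All libraries, WT included, were drawn anew from the WT means with the spread of the fit of all groups. The simulated controls thus do not have the spread of the real WT libraries. The covariance was 0.187 against 0.0505 in the simulations, a difference of 0.137. The same sign was seen for 66.8% of the genes and for 66.8% in the simulations. WT has 3 libraries, so the controls could not be split into groups of at least 2, and part of the excess may come from the shared controls. The correlation was 0.471 without large 2, 0.530 without dwarf 3 and 0.747 without WT 3, where the covariance was 0.389.

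A single gene outside the regions stood apart in both comparisons with WT and was singled out after its values were seen. AT3G04650 (chromosome 3, 1261857 to 1264687) had 1555, 1953 and 1972 counts in dwarf 1, 2 and 3 and 1557, 1670 and 1760 in large 1, 2 and 3, against 240, 187 and 217 in WT 1, 2 and 3. Its log2 fold change against WT was 3.07 (SE 0.16, adjusted p = 0.000265) for dwarf and 2.91 (SE 0.16, adjusted p = 0.000401) for large. It passed the test under each of its 20 alternatives in both comparisons.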

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

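The comparison of libraries labelled dwarf with those labelled large, and the tests of low-count genes and of expression tertiles in the raised regions, were set before their results were seen. The other tests in this part were chosen only after the result was seen.

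Genes of 4 chromosome regions stood near 1.5-fold above WT in RNAi libraries, with 12 of 14 raised segments within 0.1 of the log2 of 1.5 (0.58), and dwarf 1 stood near 2-fold on chromosome 4. The remaining segment, of 24 genes on chromosome 4 in large 3, stood at 1.80-fold and fits neither value. Normalization or library size moves whole libraries, and so makes no step within a chromosome. The smallest step between a raised segment and the rest of its own chromosome was 0.54 on the log2 scale. The search kept only steps of at least 0.2, so this value is not a separate test. Reads lost over a segment from another accession would lower genes, whereas at least 89.2% of the genes of each raised segment lay above WT. These segments were chosen for being raised, so that share is not an independent test either. Steps set by highly expressed genes only would be missing in the lowest tertile of expression, where the median step was 0.63. The tertiles hold the genes that the search itself used, so this value is not independent of the choice of segments. Extra copies of these segments are a candidate explanation, since genes under 5 CPM, which were not used to find the steps, showed a median step of 0.62 (range 0.57 to 1.03). That is a hypothesis found and tested on the same counts, which hold no DNA, so a regional change in transcription stays open, as does any tie of these segments to the transgene or to the growth of the plants.

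AT3G04650 was at least 6.48 times as high, in counts, in each RNAi library as in any WT library. A raised segment around it is argued against by its 10 tested neighbours, whose median log2 fold changes were 0.089 (range -0.08 to 0.33) in dwarf and -0.00 (range -0.22 to 0.53) in large. Shared reads are argued against by 0% of its 50-bp words being found elsewhere in the genome, with no overlapping gene. An insertion at the gene and an effect of the transgene elsewhere cannot be told apart, because all 6 libraries with the transgene show it. No biological explanation beyond the transgene was tested.

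A fall of PPD3 in the RNAi libraries was not detected. In the libraries labelled large a fall hidden by the raised end of chromosome 1 is argued against, since that region's highest median there was 0.016 on the log2 scale. A swap of single RNAi and WT libraries is argued against as well, since the lowest chromosome 4 median of the RNAi libraries lay 0.56 above the highest of the WT libraries. An exchange of whole groups would give the same separation. It would not bring out a fall either, since no difference between groups passed edgeR's test. The adjusted p was 0.708 for large against WT, 0.934 for dwarf against WT and 0.558 for dwarf against large. In the libraries labelled dwarf the fold change with the regional step taken out was -0.33 (adjusted p = 0.327, with a range of 0.327 to 1 over its alternatives), so a fall hidden by the region cannot be told apart from none. Hairpin reads counted at the gene also stay open, because the counts do not separate them, and for large against WT the 95% interval reached down to -0.56.

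For each comparison the 6 libraries can be split 3 against 3 in 10 ways, which is too few for a share under 0.05. The real split was the 1 split with the most genes for dwarf against WT (1740, highest other 0) and likewise 1 for large against WT (838, highest other 0). For dwarf against large 2 splits called at least the 129 genes of the real split, the highest other being 898 when dwarf 1, dwarf 2 and large 2 were set against the other 3 libraries, which points to a structure of the samples other than the labels. As many lists as in the real split were called by 3 splits for dwarf against WT (9, highest other 9), by 6 for large against WT (8, highest other 9) and by 2 for dwarf against large (12, highest other 13).

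The direct test between dwarf and large, which is a test of whether their changes from WT differ, passed for 129 genes by edgeR and for 12 lists by camera with a preset correlation. It passed for 0 lists with an estimated correlation or by fry, and for 0 genes with only the 2 groups in the fit, with the replicate number as a block, or without dwarf 2, large 1 or WT 1. The named genes higher in dwarf were MAM3 (log2 fold change 1.77), TIM17-1 (1.60), CHX16 (1.52), G6PD4 (1.39), ZIP5 (1.38) and CYP79F2 (1.17), of which TIM17-1, G6PD4 and ZIP5 lost the call with regional offsets. Those lower in dwarf were 4CL8 (-2.59), ATSDI1 (-1.83), XTH31 (-1.81), BT1 (-1.40), COR15A (-1.39), RD29A (-1.07), MYC2 (-0.91) and UPOX (-0.72). Reads outside annotated genes, which no comparison used, made up 0.900%, 0.776% and 0.738% in dwarf 1, 2 and 3 and 0.697%, 0.874% and 0.671% in large 1, 2 and 3, each above the 0.642 to 0.667% of the WT libraries.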

How the results depend on the processing

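The alternatives that leave out the raised regions or take out their steps were chosen after seeing the data. The others were set beforehand. The counts of genes called in dwarf against WT, large against WT and dwarf against large (main 1740, 838 and 129) were 467, 2205 and 0 with only the 2 groups in the fit, 3118, 1792 and 1677 by DESeq2, 4626, 4192 and 3781 by limma voom, 587, 265 and 67 with the regions left out, and 556, 263 and 63 with a change of at least 2-fold. With regional offsets they were 855, 327 and 169. Leaving out 1 library gave 266 to 4477, 9 to 1599 and 0 to 3236 genes. The wider counts of voom went with unequal weights, from 0.164 for dwarf 3 to 2.82 for large 1. The fits with fewer libraries or groups estimate the spread from fewer samples, which does not account for the counts that rose. These include 2205 for large against WT with only the 2 groups, and 4477 for dwarf against WT without dwarf 3. The main fit also pools groups of unequal spread. Between replicates the Pearson correlation of log2 CPM was 0.986 to 0.992 in WT, 0.977 to 0.989 in large and 0.950 to 0.977 in dwarf. What caused each change was not tested.

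The replicate number as a block gave 1263, 618 and 0 genes. Same-numbered libraries did not deviate together throughout. The correlations were -0.14, 0.08 and -0.03 for dwarf and WT, 0.04, 0.08 and -0.07 for large and WT, and -0.24, -0.07 and 0.43 for dwarf and large. Dwarf 3 correlated more with large 3 (0.43) than with any other large library (highest 0.21). Dwarf 1 correlated most with large 2 (0.57), so not every library correlated best with its own number. The numbers are therefore not taken as pairs. The block kept 105 of 139 named gene results other than those of PPD3 on their side of the threshold, with 34 calls lost, and all 29 list calls.

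The lists called (9, 8 and 12) fell to 0 in each comparison with an estimated correlation and were 1, 4 and 0 by the directional fry test, while its mixed test, of change in either direction, called 12, 7 and 10. Camera's calls thus rest on its preset correlation. Without 1 library 7 to 10, 6 to 9 and 9 to 13 lists were called, not always the same ones, and 10, 9 and 12 with regional offsets.

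PPD3 in dwarf against WT (0.03) changed sign with upper-quartile factors (-0.042), no filter (-0.00302) and regional offsets (-0.33), and lay between -0.15 and 0.14 without 1 library, with adjusted p from 0.327 to 1. In dwarf against large it was -0.16 with regional offsets (adjusted p from 0.119 to 0.965 over its alternatives), and in large against WT it stayed negative, with adjusted p from 0.248 to 0.944. SUVH9 in the raised region of chromosome 4 changed sign with regional offsets, to -0.24 in dwarf against WT and -0.061 in large against WT. The correlation of the changes from WT ranged from 0.471 to 0.747 without 1 library. Over all named genes other than PPD3 and all alternatives, 2073 results were on the same side of the threshold, 566 lost the call, 100 gained it and 2 changed sign, and for lists 389 held and 75 lost it. The alternative without plastid, mitochondrial and rRNA genes changed no count, as the 285 genes removed were plastid and mitochondrial ones with 0 counts. No nuclear rRNA gene was among them, so the effect of such genes was not tested. In simulated data of this depth 11 of 50 genes changed 1.5-fold were recovered for dwarf against WT, so smaller changes may lie among the genes not called.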

Other observations

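The tests in this part were chosen only after the results were seen, from genes that stood out in the comparisons, and 2 lists were drawn up and tried. ATSDI1 and LSU3 prompted the sulfur list and ACO1 and LBD41 the low-oxygen list, so camera was run without these 4 genes. Its p-values are single and unadjusted for the choice of lists. Of 13 tested genes of the response to sulfur deficiency, 8 rose in the libraries labelled large against WT and all 13 were positive, with a median log2 fold change of 0.88. Without the 2 prompting genes 6 of the remaining 11 rose, with a median of 0.83 (camera p = 1.86e-08, p = 0.0115 with an estimated correlation). LSU1 rose by 2.67, ATSDI1 by 2.36 and LSU3 by 1.76, all genes known to respond to low sulfur, and the sulfate reduction gene APR1 (chromosome 4 region) by 0.88. In the libraries labelled dwarf 3 of the 13 rose, namely the sulfate transporter gene SULTR1;2 (3.3, end of chromosome 1), LSU1 (1.78) and APR1 (0.77). For the 11 genes other than the prompting ones the camera p in dwarf was 0.00788 (p = 0.141 with an estimated correlation). With regional offsets APR1 stood at 0.30 in large and 0.05 in dwarf and was not called. The direct comparison of dwarf with large gave a camera p of 0.000902 without the prompting genes (p = 0.0783 with an estimated correlation). The single gene called among the 13 was the prompting gene ATSDI1, lower in dwarf.

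Of 14 tested genes of the core response to low oxygen, 4 rose in dwarf against WT. They were ACO1 (2.08), LBD41 (1.74, chromosome 3 region), the haemoglobin gene HB1 (0.92) and the sucrose synthase gene SUS4 (0.91). Without the prompting genes ACO1 and LBD41, 2 of 12 rose (camera p = 0.000817, p = 0.116 with an estimated correlation). In large against WT 3 rose, which were ACO1 (2.7), LBD41 (2.53) and SUS4 (1.08). Without the prompting genes 1 of 12 rose (camera p = 0.000310, p = 0.0952 with an estimated correlation). Dwarf and large did not differ past the threshold in this list without the prompting genes (camera p = 0.831, p = 0.911 with an estimated correlation). Of all 14 genes, 0 were called between dwarf and large by edgeR. With regional offsets LBD41 stood at 1.55 in dwarf and 1.98 in large and was not called, and the calls of HB1 and SUS4 in dwarf were lost. The calls of LSU1, ATSDI1 and LSU3 in large against WT were lost without WT 1 and without WT 2 (adjusted p up to 0.0732), and each of the hypoxia calls without several libraries.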
